A study of Homo sapiens with 12 samples.

How the data were processed

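Jurkat cells, an established line derived from a T cell acute lymphoblastic leukaemia, were treated for 8 h and their polyadenylated RNA was sequenced from the 3' end with the QuantSeq REV kit, per the labels' protocols. The labels name 12 libraries in 4 groups of 3. One group received a CDK12 degrader at 50 nM, another its negative control compound at 100 nM, another the CDK12 and CDK13 inhibitor THZ531 at 250 nM, and the last DMSO. The labels conflict on the degrader's name, which the protocol and the design text give as BSJ-4-116 and the treatment tag gives as BSJ-4-23. The design text says that the work was done in triplicate, while the extraction protocol speaks of biological duplicates, so whether the libraries of a group came from separate cultures is not settled here.

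The data used here are 1 deposited list of peaks that the authors called on all 12 libraries together, per the labels. Each peak has a start, an end, a summit, a fold enrichment over the local background, which is a ratio as the authors' peak caller deposited it, and a −log10 p and −log10 q, also as the authors deposited them. The list has no strand and no column for a library or a group. The fold enrichment and −log10 values therefore serve only to describe, rank and filter peaks within the list. The submitters' processing notes name STAR 2.5.1b, SAMtools, deepTools 2.5.4, MACS2 2.1.1 and the build GRCh38, with no settings. The number of reads per library, the handling of reads at the same position and the threshold are not given in the sources used here. THZ531 against DMSO and the degrader against its negative control compound are the comparisons the design names, and neither was made, because a value per library or per group was not analysed here.

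The pileup of reads at each summit was recovered from the deposited values, taking the fold enrichment as pileup plus 1 over background plus 1 and p as the Poisson probability of a larger pileup. Every whole pileup up to 600 was tried, and for all 98990 peaks 1 was found whose −log10 p lay within 0.001 of the deposited value. The form of that equation is an assumption about the peak caller that this match tests.

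Each peak was placed by its summit on GENCODE 29, which uses GRCh38. The classes, in order of priority, were the terminal exon of a protein-coding transcript (its last exon or 3' untranslated region), 1000 bp past the end of a protein-coding gene, an internal exon, an intron, an exon of another gene, an intron of another gene, and intergenic. Only transcripts of the GENCODE basic set with a complete end were used. Strand was ignored, and 7840 summits (7.92%) lay in gene records of both strands. Intergenic means outside the transcripts used, and 1724 of these peaks lay inside the longer record of a gene. A polyadenylation signal was AATAAA or ATTAAA on the gene strand within 100 bp of the summit, and an A-rich stretch was at least 15 A in 20 bases within 150 bp. Both were set against windows moved by 1000 bp in either direction and, in internal exons, also against random positions in the same exons. Windows at a summit stopped at the end of the annotated transcript, while moved windows were used only at full length. In internal exons and introns the longest transcript was taken, and moved windows could lie in its other exons. Sequence came from annotated transcripts, because a genome sequence was not used here. This limits the sequence results in introns to 2626 of 48877 peaks (5.37%), those that lie in an exon of a transcript of the same gene outside the set used for placement, and such transcripts were in part annotated because they end there.

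Gene lists were set against 10000 random lists of the same size, drawn from genes with a terminal exon peak in the same of 20 gene length bins, and only percentiles are given, since genes are not replicates. Lists were not matched on having introns, and a gene without an intron cannot have an intronic peak. A total of 16 lists were used, and the 9 with at least 5 members with a terminal exon peak were compared with random lists. The position of intronic peaks was set against positions drawn evenly from the introns of the same genes, with an interval from 200 bootstrap draws of genes. Intervals of shares are 95% Wilson intervals, and those of differences are Newcombe's. They cover counting error only, since neighbouring peaks share reads and the peaks come from 1 pooled set.

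The genes named were chosen by a rule which, like the lists, was fixed before the data were examined. It takes the drug targets, the 4 genes of each list with the most intronic peaks (ties by fold enrichment), or for marker and non-polyadenylated lists up to 4 with the highest fold enrichment, the 10 genes with the highest fold enrichment, and the 10 genes with the most intronic peaks. Any list member may be named as having no peak, and genes named outside the rule are said to be so. The result of 1 gene that the rule takes is not reported here. Alternatives covered the peak threshold, merging, the position that stands for a peak, genes on both strands, the definitions of signal and A-rich stretch, the distance past the gene end and the matching of random lists.

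The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were first tested on simulated data. All 1800 peaks simulated on 400 made-up genes were placed in the class and gene they were made for, and all 3399 simulated pileups were recovered exactly. Of 100 unchanged lists of 48 long genes among 12000 genes, 96.0% lay between percentiles 2.5 and 97.5 of the random lists, and 100% of lists with thinned intronic peaks lay below percentile 2.5. Lists with an excess of intronic peaks were not simulated. Signals and A-rich stretches planted in 600 of 1000 sequences were found in 60.0%. For 20000 positions drawn evenly from introns of 9720 genes the median difference was 0.0048 (-0.0058 to 0.0138), and for positions drawn toward the gene start in 9729 genes it was -0.0313 (-0.0382 to -0.0240).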

Results

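The 3' ends of polyadenylated RNA were mapped in Jurkat cells, a human T cell leukaemia line, after 8 h with DMSO, THZ531 at 250 nM, a CDK12 degrader at 50 nM or its negative control compound at 100 nM, with 3 libraries each. CDK12 and CDK13 are kinases that act with cyclin K on RNA polymerase II during elongation. The design asks what inhibition or loss of CDK12 does to polyadenylated transcripts. The peak list analysed here gives 1 value per peak for all 12 libraries together, so it holds no replicates, and neither THZ531 against DMSO nor the degrader against its negative control compound was compared. What follows describes where reads of the pooled libraries, treated and untreated alike, formed peaks, and a peak is not by itself an end of a polyadenylated RNA.

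The list held 98990 peaks, of which 98748 lay on assembled chromosomes, 154 on scaffolds and 88 on 72 of the ERCC spike-in RNAs. Median width was 104 bp (range 100 to 1763). The authors' fold enrichment had a median of 6.25 (quartiles 5.26 and 8.13) and −log10 q in the authors' deposited table a median of 6.52, with a lowest value of 1.31. The pileup recovered from these values had a median of 9 reads (quartiles 6 and 13), and ranged from 3 to 198.

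**Figure D1:**
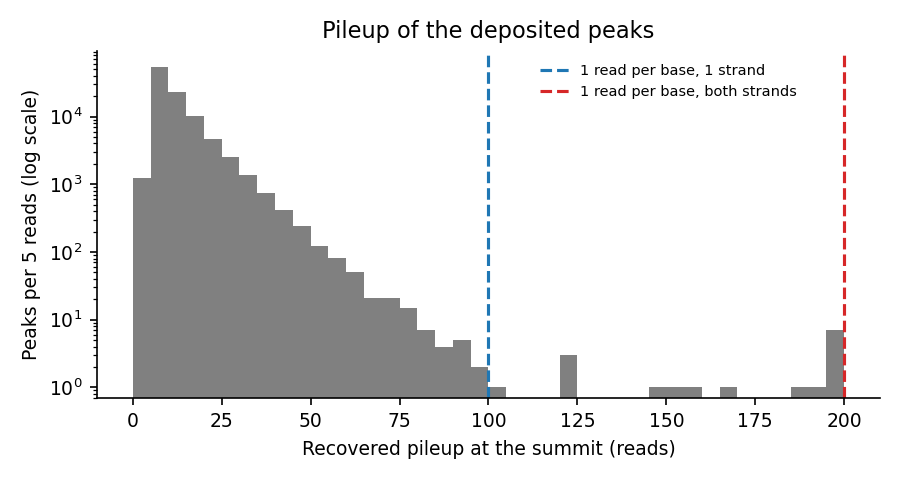
Number of peaks (log axis) against the pileup at the summit, in reads, recovered from the authors' fold enrichment and p value. Dashed lines mark 1 read per base of a 100 bp extension on 1 strand (100) and on both (200), and the highest pileup was 198.

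Terminal exons of protein-coding genes had the highest median pileup of the classes, and introns held the largest number of peaks. The shares below were not divided by the length of each class. Introns summed to 649 Mb in genes with a terminal exon peak and 508 Mb in genes without one. Terminal exons contained 20627 peaks (20.8%, 20.6 to 21.1) with a median pileup of 15 and a median fold enrichment of 8.28. Introns of protein-coding genes contained 48877 (49.4%, 49.1 to 49.7) with a median pileup of 8 and a median fold enrichment of 6.0. Internal exons contained 4453 peaks (4.50%), and 1008 (1.02%) lay within 1000 bp past a gene. Exons of other genes held 2707 peaks (2.73%), introns of other genes 5653 (5.71%) and intergenic sequence 15665 (15.8%). Among peaks with a −log10 q of at least 10 the terminal exons held 45.0% and introns 30.5%, and among the 49495 peaks of highest fold enrichment the terminal exons held 31.9%.

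**Figure D2:**
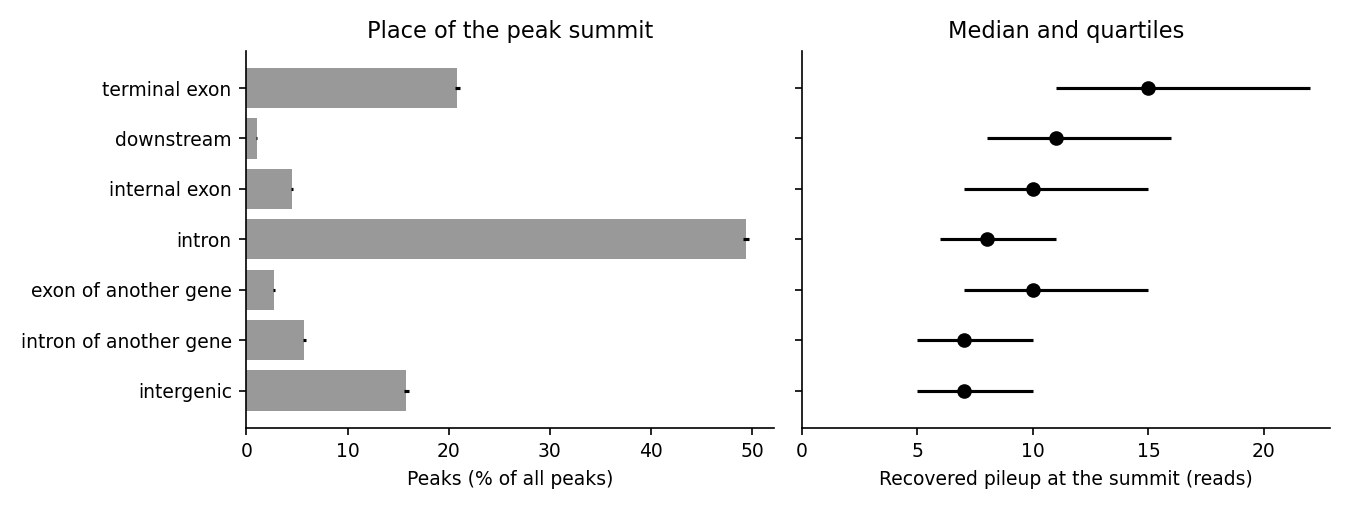
Left, percent of the 98990 peaks with the summit in each annotation class, with 95% Wilson intervals. Right, median and quartiles of the recovered pileup at the summit, which was highest in terminal exons (15 reads) and lower in introns (8 reads).

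Most peaks in terminal exons lay just upstream of annotated transcript ends and beside polyadenylation signals. Of 19932 such peaks in 1 gene, 57.0% had their summit 0 to 150 bp upstream of an annotated end, at a median of 53 bp, against 18.0% of random positions in the same exons (difference 39.0 percentage points, 38.1 to 39.8). A signal lay within 100 bp of 74.7% of terminal exon summits (74.1 to 75.3, 19928 peaks) against 20.7% of moved windows, AATAAA alone accounting for 59.2%. In means over 5 bases the most frequent start of AATAAA or ATTAAA was 28 bp downstream of the summit. Annotated ends, where within 150 bp, lay further downstream than this, at a median of 53 bp. An A-rich stretch was present at 13.9% of terminal exon peaks, whose windows were cut at the transcript end, against 6.96% of full moved windows. This share depended on the definition, at 55.8% (moved windows 40.6%) with at least 12 A in 20 bases and 6.96% (moved windows 4.16%) with 10 A in a row.

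Fewer internal exon peaks had a signal. It was found at 29.5% of 4393 internal exon peaks against 19.8% of moved windows (difference 9.71 points, 8.03 to 11.4) and 25.4% of random positions in the same exons (difference 4.03 points, 2.16 to 5.89). An A-rich stretch was found at 16.6% against 5.58% of moved windows (difference 11.04 points, 9.80 to 12.3) and 13.7% of random positions in the same exons (difference 2.91 points, 1.41 to 4.41). For the 2626 intronic peaks with transcript sequence, 55.2% had a signal (53.3 to 57.1) against 16.4% of moved windows, and 21.1% had an A-rich stretch (19.6 to 22.7) against 4.72%. With 14 hexamers the signal share was 86.0% (moved windows 57.5%), and the A-rich share was 61.3% (34.2%) with 12 A in 20 bases and 10.9% (1.92%) with 10 A in a row. These 2626 lie in annotated exons of other transcripts and do not stand for the remaining intronic peaks. Their moved windows could lie in other exons of the spliced transcript.

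**Figure D3:**
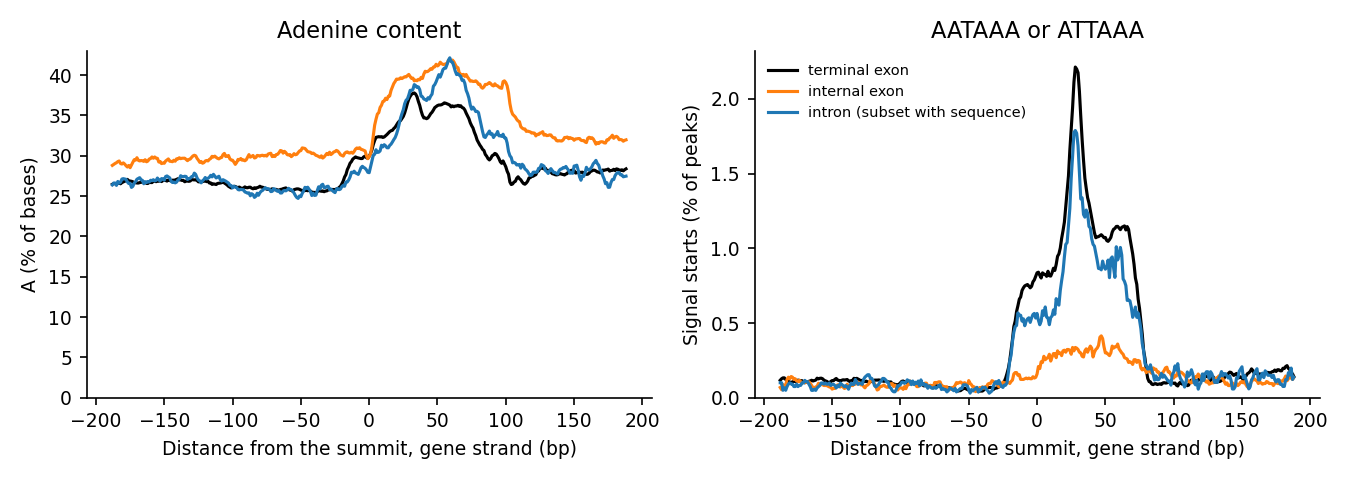
Percent of A (left) and percent of peaks with AATAAA or ATTAAA starting at each base (right) against distance from the summit on the gene strand, in means over 5 bases. At each distance only peaks whose transcript still has sequence there are counted, so upstream and downstream values come from partly different peaks. A made up 34.1% of bases 10 to 99 bp downstream of terminal exon summits and 26.5% of the 100 bp upstream. These shares were 39.7% and 30.2% in internal exons, and 36.2% and 26.0% in the intronic subset. Higher A content downstream was thus not particular to terminal exons. Signals were most frequent at 28 bp in terminal exons and in the intronic subset.

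Of 19607 protein-coding genes, 11740 (59.9%) had a peak in a terminal exon, and 5725 of these (48.8%, 47.9 to 49.7) had several. Intronic peaks were present in 8255 of the 11740 genes (70.3%, 69.5 to 71.1), at 69.1 per Mb of intron. With only peaks of a −log10 q of at least 10 the share with an intronic peak was 36.8% and that with several terminal exon peaks 28.4%. In the 7867 genes without a terminal exon peak, 26.8% had an intronic peak and the density was 10.4 per Mb, 6.64 times lower. When the genes with a terminal exon peak were divided into 5 equal groups by length, 16.7, 58.1, 85.6, 93.6 and 97.6% had an intronic peak from shortest to longest, while the density was 72.5, 80.6, 86.3, 83.5 and 62.0 per Mb.

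The 10 genes with the most intronic peaks had between 60 and 84 each. ARHGAP15, a Rac GTPase-activating protein gene, had 84 intronic peaks, the oxidoreductase gene WWOX 77, LDLRAD4 71, the guanine exchange factor gene VAV3 67, GMDS 65, the protein kinase C gene PRKCA 64, ELMO1 64, SMYD3 63, CDH4 63 and AFF3 60. ARHGAP15 spans 677 kb and WWOX 1113 kb. Along genes, intronic peaks lay slightly closer to the start than places drawn evenly from the same introns, at a median relative position of 0.444 against 0.479 (difference -0.0347, -0.0416 to -0.0284, 47705 peaks in 9866 genes). Of 10 equal parts of the gene, the one at the start held 1.29 times as many peaks as drawn places and the one at the end 0.719 times as many.

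All 3 genes of the drug target list had peaks inside their terminal exons and inside their introns. CDK12 (ENSG00000167258.13, chromosome 17, 39461511 to 39564907, GRCh38) had 6 terminal exon peaks, the first starting at 39531320 and the last ending at 39534544, with fold enrichments from 5.20 to 7.33, and 5 intronic and 2 internal exon peaks. Its intronic peak at 39495381 to 39495489 had a higher fold enrichment, 10.6, than any of its terminal exon peaks, but its pileup of 16 was below the 19 of the terminal exon peak at 39532167 to 39532273. CDK13 (ENSG00000065883.15, chromosome 7, 39949646 to 40099580) had 2 terminal exon peaks, the stronger at 40095431 to 40095552 with a fold enrichment of 14.1, and 17 intronic peaks. CCNK (ENSG00000090061.17, chromosome 14, 99481169 to 99535044), which encodes cyclin K, had 3 terminal exon peaks, the strongest at 99512031 to 99512194 with a fold enrichment of 18.0, 1 internal exon peak and 6 intronic peaks. The last 4 of the CCNK intronic peaks lay past that terminal exon, in the intron of a longer transcript.

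**Figure D4:**
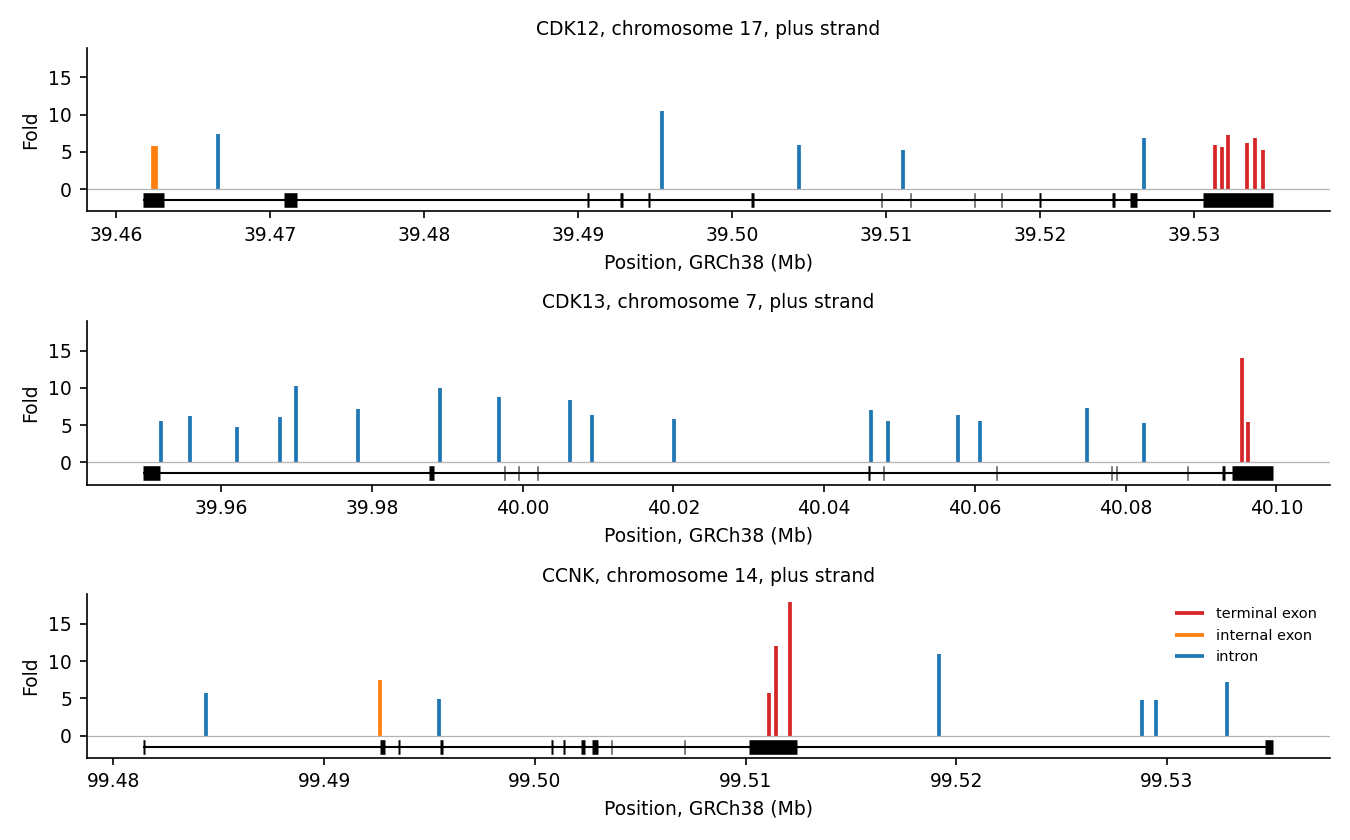
Peaks of CDK12, CDK13 and CCNK by summit position (GRCh38, Mb) with the authors' fold enrichment as height and colour for class, above the exons of the transcripts used (boxes). CDK12 shows 6 terminal exon peaks, CDK13 shows 17 intronic peaks and CCNK has its strongest peak, fold enrichment 18.0, within the gene span.

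DNA damage response genes, the group whose expression is best known to depend on CDK12, had terminal exon peaks in 48 of 50 members. Of these 48, 40 (83.3%, 70.4 to 91.3) also had an intronic peak, against a median of 85.4% (77.1 to 93.8) in random lists of the same length, which is percentile 26.0. With only peaks of a −log10 q of at least 10 the share was 45.0%, at percentile 22.2. Their median was 4 intronic peaks per gene against 3.5 in random lists (percentile 72.6). RAD51B, a homologous recombination gene, had 46 intronic peaks, REV3L, the catalytic subunit of DNA polymerase zeta, 21, the helicase gene BRIP1 18 and the Werner syndrome helicase gene WRN 17. RAD51B spans 910 kb, and its only terminal exon peak had a pileup of 5. Named outside the rule after their values were seen, BRCA1 had 4 intronic and 3 terminal exon peaks, BRCA2 6 and 2, and ATM 8 and 2. Against random lists that were not matched on length, the share lay at percentile 98.1.

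Other groups tied to transcription and 3' end formation were likewise within the range of their random lists. Terminal exon peaks were found for all 23 cleavage and polyadenylation factors, and 78.3% of these had an intronic peak (percentile 59.5), among them the cleavage and polyadenylation complex genes FIP1L1 with 13 and WDR33 with 9, and SCAF8 with 12 and SCAF4 with 8. Other transcription kinases and elongation factors had terminal exon peaks in 23 of 25, of which 78.3% had an intronic peak (percentile 72.3), among them MNAT1 with 18, CDC73 with 15 and CDK8 with 13. Both lists had a median of 3 intronic peaks per gene against 2 in random lists. That lay at percentile 79.4 for the cleavage and polyadenylation factors and 85.8 for the kinases and elongation factors. LEO1 had no terminal exon peak in the list but 2 internal exon and 3 intronic peaks, and POLR2A had no exon or intronic peak. Among 8 genes with described intronic polyadenylation all had intronic peaks (percentile 69.0), with 47 in FOXN3, 46 in CHST11, 14 in DICER1 and 10 in MGA. The random lists also had a median share of 100%, so this share could not lie above their range. The median of 9 intronic peaks per gene in these 8 genes compared with 6 in random lists (percentile 89.4).

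**Figure D5:**
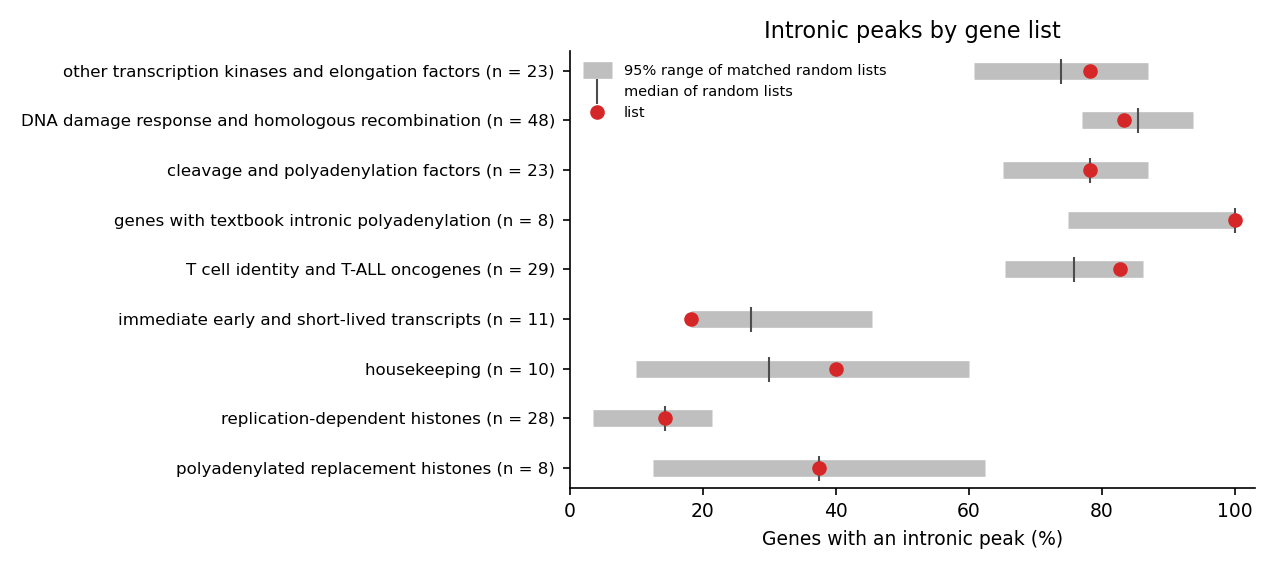
Percent of genes with an intronic peak among the members of each list that have a terminal exon peak (red points), with the median (tick) and 95% range (grey) of 10000 random lists matched on gene length. For DNA damage response genes the share was 83.3% and the median of the random lists 85.4%.

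T cell genes were well represented, and markers of other lineages were mostly without terminal exon peaks. Of 32 protein-coding members of the T cell and T-ALL list, 29 had a terminal exon peak, and CD8A, LMO2 and LYL1 had none. The T cell receptor constant genes TRAC, TRBC1 and TRBC2 each had 1 exon peak. These 29 genes had a median of 4 intronic peaks against 2 in random lists (percentile 97.6, the highest of the 9 lists compared), with 48, 22 and 17 in the transcription factor genes RUNX1, BCL11B and LEF1 and 16 in PTPRC, which encodes CD45, while the share with any intronic peak, 82.8%, lay at percentile 87.3. RUNX1 spans 1217 kb. For this list the random lists were matched on gene length and not on peak strength. The median highest terminal exon pileup was 31 in T cell genes, against 19 in all nuclear protein-coding genes with a terminal exon peak. Whether the higher count of intronic peaks follows from this was not tested. None of the 8 myeloid markers and none of the 7 erythroid markers had a terminal exon peak. Among 6 protein-coding B cell markers BLK and CD79A had 1 each, IGHM had 2 exon peaks, and of 9 fibroblast and epithelial markers COL1A1 had 2. Of the markers without a terminal exon peak, CSF1R had 3 intronic peaks, and PAX5, HBG2 and CDH1 had 1 each. A missing peak does not by itself show that a gene was not expressed.

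Immediate early and housekeeping genes had terminal exon peaks throughout. All 11 immediate early and short-lived transcripts had a terminal exon peak and 18.2% had an intronic one (percentile 16.3), with 9 in CCND3, 3 in ATF3 and 0 in EGR1 and JUNB. All 10 housekeeping genes had a terminal exon peak and 40% an intronic one (percentile 68.6), with 10 in PGK1, 3 in RPL3, 2 in RPS3 and 1 in B2M.

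Peaks, placed without regard to strand, were also present at genes listed here as making RNAs without a poly(A) tail. Whether any of these genes also made RNA with a tail was not tested. Replication-dependent histone genes, whose messages end in a stem-loop, had a terminal exon peak in 28 of 71 (39.4%, 28.9 to 51.1), led by HIST1H4C with a fold enrichment of 22.2, HIST1H4J with 14.2, HIST1H1C with 13.1 and HIST2H2AC with 10.7. With only peaks of a −log10 q of at least 10 the share was 16.9%, and with the 49495 peaks of highest fold enrichment it was 18.3%. All 8 replacement histone genes, which have polyadenylated messages, had one, with fold enrichments of 26.0 in H2AFY, 20.5 in H2AFZ, 11.9 in H2AFV and 9.86 in H3F3A. The share with an intronic peak was 14.3% in the 28 replication-dependent genes (percentile 63.3) and 37.5% in the 8 replacement genes (percentile 61.0). Random lists were not matched on having introns, so these percentiles cannot be told apart from gene structure. In a gene of a single exon, the terminal exon is the whole gene. Of 11 small non-coding RNA genes without a tail, 9 had an exon peak, with fold enrichments of 25 in RN7SK, 18.3 in RPPH1, 17.3 in RNU2-1 and 14.7 in RNU4-2, and RNU1-1 and RNU5A-1 had none. The RNU2-1 peak also lay in an intron of CCDC200, a gene named here after its values were seen. In a separate list, not chosen for lacking a tail, the nuclear non-coding RNAs MALAT1, NEAT1 and KCNQ1OT1 had 7, 5 and 5 exon peaks.

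The highest fold enrichments in protein-coding genes lay partly at gene ends and partly in introns. MTA1, a chromatin remodelling subunit gene (31.2), ANO10 (30.9), the ATP synthase subunit gene ATP5PO (30.1) and the leukocyte integrin gene ITGB2 (29.8) reached their highest value in a terminal exon. The kinesin gene KIF5C (40), PDZRN4 (39.2), UNC5D (33.5), DGKI (32.5) and DLG2 (31.3) had no terminal exon peak, and their highest value was in an intron. HECTD4 reached 38.5 in an intron against 13.5 in its terminal exon. The KIF5C peak lay at 148881731 to 148881918 on chromosome 2 and the PDZRN4 peak at 41363590 to 41363779 on chromosome 12.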

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

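The settings with all protein-coding transcripts, and with intronic peaks in an exon of another gene left out, were chosen after seeing the data. Of 86 values under alternatives, 48 stayed within the interval or range set for the main value, 37 moved beyond it, 1 passed the percentile limit, and 0 changed direction. Merging peaks within 50 bp and using the middle of the peak moved none. No paired analysis was possible because the peak list pools all 12 libraries, and for the same reason no library could be left out.

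With a −log10 q of at least 10, 26318 peaks remained. Terminal exons then held 45.0% and introns 30.5%, the opposite order to the full list, where they held 20.8% and 49.4%. Of genes, 36.8% had an intronic peak and 28.4% several terminal exon peaks. For DNA damage response genes the share was 45.0% and for replication-dependent histones 16.9%. A signal was found at 81.0% of terminal exon and 66.7% of intronic peaks, and an A-rich stretch at 13.0% and 19.6%. With the 49495 peaks of highest fold enrichment, the same quantities were 31.9, 41.6, 56.1, 39.2, 67.4, 18.3, 78.8 and 61.2%, and an A-rich stretch at 13.2% of terminal exon peaks, while the position difference was -0.0441.

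With only the 76642 peaks in gene records of 1 strand, which leaves out 7840 in records of both strands and 14508 in no gene record, terminal exons held 22.7% and introns 59.3%, 47.3% of genes had several terminal exon peaks and the position difference was -0.0440. Counting 5000 bp past the gene end with terminal exons gave 24.7%, all protein-coding transcripts gave 21.4% (21.35), and leaving out intronic peaks in an exon of another gene gave 48.1% in introns.

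A signal within 50 bp was found at 59.95% of terminal exon and 44.6% of intronic peaks. With 14 hexamers the shares were 96.2% and 86.0%, but moved windows then reached 65.3% and 57.5%. With at least 12 A in 20 bases the A-rich shares were 55.8% and 61.3% (moved windows 40.6% and 34.2%), and with 10 A in a row 6.96% and 10.9% (moved windows 4.16% and 1.92%). The DNA damage response share lay between percentiles 22.2 and 42.5 under every matched setting, and at percentile 98.1 when random lists were not matched on length.

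Settings that leave out intronic peaks with an A-rich stretch, or without a signal, were not run, because most intronic peaks had no sequence here. For the values that moved, the cause was not tested. The depth of single libraries is unknown.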

Other observations

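The comparison of peaks within 1 terminal exon, the pileups by gene list, the spike-in test and both tests on intronic peaks away from the end of the transcript used were chosen after related results had been seen.

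Terminal exons with several peaks differed in signals along their length. In 4988 such exons the peak nearest the exon's end had a polyadenylation signal in 85.6% of cases, against 60.3% of the 7719 peaks before it (difference 25.3 percentage points, 23.8 to 26.7), and an A-rich stretch in 11.01% against 20.1% (difference -9.07, -10.3 to -7.82). Windows stopped at the transcript end, so last peaks were searched over fewer bases. The lower A-rich share may follow from that alone, and no conclusion is drawn from it. The last peak also had the highest fold enrichment of its exon in 49.9% of exons (48.5 to 51.3), where equal chances would give 42.5%. By list, the median over genes of the highest terminal exon pileup was 38 for housekeeping genes, 33.5 for replacement histones, 31 for T cell genes, 28 for immediate early genes, 26 for the drug targets and for other transcription kinases and elongation factors, 23 for cleavage and polyadenylation factors and for genes with described intronic polyadenylation, 20 for DNA damage response genes, 12.5 for replication-dependent histones and for the 2 B cell markers, and 10 for COL1A1, against 19 for the 11736 nuclear protein-coding genes with a terminal exon peak. Genes had from 1 to 9 terminal exon peaks, and the highest of several lies higher by construction, so these medians do not rank abundance.

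Pileups stopped at a fixed height, and no biological explanation of this was tested. The highest recovered pileup was 198, in the mitochondrial gene MT-ND5, where a 100 bp extension of reads counted once per position and strand allows at most 200. Only 8 nuclear peaks exceeded 100, the limit for 1 strand, all on chromosome 1 between 629089 and 634921 among pseudogenes of mitochondrial genes such as MTND2P28, and the highest of the others was 97. These values are consistent with reads at the same position having been counted once, which the sources used here do not state. If so, fold enrichment would understate abundant RNAs, and mitochondrial peaks had fold enrichments of 1.339 to 3.50.

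Many peaks lay away from annotated 3' ends, and priming of oligo(dT) at A-rich stretches is a candidate explanation beside polyadenylation at other sites. In internal exons the share of peaks with an A-rich stretch exceeded that of random positions in the same exons by 2.91 points (1.41 to 4.41) and that of moved windows by 11.04 points (9.80 to 12.3). Among intronic peaks with sequence and more than 150 bp from the end of the transcript used, 25.4% of 1349 had an A-rich stretch, 19.8 points above moved windows (17.02 to 22.5), and of the 1007 without one 48.1% had a signal, 32.6 points above moved windows (28.7 to 36.4), so both explanations stay open and may each hold for part of these peaks. For introns no random positions in the same exons were drawn, and moved windows could lie in other exons. The size of both excesses is therefore uncertain, since in internal exons the same-exon positions gave the smaller A-rich excess. Of 72 spike-in RNAs, 11 had several peaks, and their median highest pileup was 37 against 18 for the 61 with 1 peak (difference 19, two-sided permutation test with 100000 resamples, p = 0.00198), which decides nothing, since the highest of several peaks lies higher by construction. Intronic peaks without transcript sequence were not tested, and neither was any effect of treatment.

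DNA damage response genes are long, and length is a candidate explanation for their intronic peaks. Their share with an intronic peak lay at percentile 98.1 of random lists that ignored length and at percentile 26.0 of lists matched on it. In the pooled libraries this share thus showed no excess beyond length. It leaves little room for one, since 97.6% of the longest group of genes had an intronic peak. The median of 4 intronic peaks per gene, against 3.5 in matched lists, lay at percentile 72.6. Whether any treatment changed the group's intronic peaks was not tested, because the peaks pool treated and control cells.

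The shift of intronic peaks toward the gene start (difference -0.0347, -0.0416 to -0.0284) remained after allowing for where introns lie, since the drawn places came from the same introns. Drawn places could, however, lie in exons of overlapping protein-coding genes, where a peak would have been placed in another class. Peaks in introns of several genes were left out. How much of this small shift follows from these placement rules was not tested. In genes without a terminal exon peak, 7 of 48 intronic peaks with a pileup of at least 30 (14.6%) lay in an exon of another gene, 4 in processed pseudogenes and 3 in small nuclear RNA genes, against 3.52% of 3607 with a pileup under 10 (difference 11.1 points, 3.70 to 23.7). The other 41 lay in no such exon, and 9 of the 48 were in CCDC200, a gene chosen here after its values were seen, whose introns hold RNU2-1.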
